A study of Schizosaccharomyces pombe with 3 samples.

How the data were processed

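The series holds 3 chromatin immunoprecipitation sequencing (ChIP-seq) libraries from the fission yeast Schizosaccharomyces pombe, collected in log phase in rich medium with glucose. The bead control was untagged chromatin incubated with beads and no antibody. The Pol II library was untagged chromatin precipitated with an antibody to the C-terminal domain of RNA polymerase II and Protein G beads. The Med7 library came from cells with TAP-tagged Med7, a Mediator subunit, and IgG beads. Each group has 1 library. The control shares neither the tag nor the IgG beads with the Med7 library, and no untagged library on IgG beads was used here.

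The authors deposited, per library, a list of aligned reads with 1 row per read, its chromosome, first and last base and strand, and no signal, score or normalisation. The submitters' processing notes name Bowtie version 0.12.7 without saying for which step. The genome build, the mismatches allowed and the treatment of reads with several hits are not given in the sources used here. They were therefore checked on the reads. Of the nuclear reads, 99.2% in the control, 99.1% in the Pol II library and 99.2% in the Med7 library spanned 45 bases. When these were placed on the nuclear chromosomes of the reference assembly ASM294v3, 0 of them in any library began at a 45-base sequence that occurs more than once in the genome. With the starts moved by 1 base, 147, 306 and 151 did. The starts were thus read as 1-based, the nuclear coordinates as those of this assembly, and the reads as uniquely placed. The mitochondrial chromosome in the files ended at base 19431 against 19433 in the reference, so only its read totals were used. Duplicate reads were present: 12.9% of nuclear reads in the control, 17.0% in the Pol II library and 16.4% in the Med7 library repeated the position and strand of another read. Repeats such as the arms of the centromeres hold few reads because reads with several hits are absent.

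Everything after the read lists was computed for this text with Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9 and BLAST 2.17.0. A fragment length of 150 bp (control), 155 bp (Pol II) and 135 bp (Med7) was taken from the strand cross-correlation of distinct read starts between 100 and 300 bp. At these lengths the cross-correlation was 0.0645 for Pol II, but 0.0036 for Med7 and 0.0032 for the control. The Med7 and control lengths thus rest on a weak signal. Each read was counted at its 5' end moved 75, 77 or 67 bp towards its 3' end. Counts were divided by the number of nuclear reads outside the ribosomal DNA repeats at the ends of chromosome III and are given as RPM, the usual scale for read counts at equal depth. Those totals were 630825 reads in the control, 1687058 in the Pol II library and 696101 in the Med7 library.

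A fold is the RPM of a ChIP library over that of the bead control in the same window. Its 95% interval is the exact conditional binomial one and covers counting error only, since PCR reads without molecular identifiers are not independent molecules. With 1 library per group no p-value across conditions can be given, and no difference has a replicate check. Each fold compares libraries, not conditions. Gene bodies ran from the annotated transcript start to its end, and 208 of the 5113 protein-coding genes had no annotated untranslated region. Promoter windows ran from 500 bp upstream to 100 bp downstream of the transcript start. A window was used when both libraries together held at least 20 reads and at least 90% of its positions started a unique 45-base sequence. A gene was counted as high at 2-fold or more with the lower bound above 1, and as low at 0.5-fold or less with the upper bound under 1. At a median of 97 control reads per gene body and 25 per promoter window, the precision differs between the window types. A list's median log2 fold used a pseudocount of 0.5 reads and was set against 10000 random lists of the same size drawn from the same deciles of control reads. The random lists were not matched on base composition.

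The fold rule was tested on simulated counts, with 44 to 50 measured genes per fold. For Pol II gene bodies (5047 genes) it recovered 100.0% of genes simulated at 4-fold, 96.0% at 2.5-fold, 0.0% at 1.5-fold and 100.0% at 0.25-fold, and called 3 of 4848 unchanged genes. For Med7 promoter windows (4957 genes) it recovered 100.0% at 4-fold, 80.0% at 2.5-fold, 18.0% at 1.5-fold and 93.2% at 0.25-fold, and called 82 of 4763 unchanged genes.

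The genome annotation used here holds no centromere features. Each centromere was taken as the longest span of a chromosome without a protein-coding gene. Its central core was the part between the innermost inverted repeat arms of at least 1000 bp, found by aligning the span to itself. The outer region began, going out from the core, at the nearest stretch of at least 500 bp that matched another centromere, and ran to the flanking gene, so it can hold unique sequence beside the repeats. The inner repeats lie between it and the core. The profile along genes used 3102 protein-coding genes of at least 500 bp whose start lay more than 500 bp from another protein-coding gene on the same strand and whose windows were at least 90% unique, in bins of 50 bp, with intervals from 1000 bootstrap draws of genes.

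The groups, comparisons, size rule, alternatives, 17 gene lists and the rule for named genes were fixed before the data were examined. The genes named are the 15 highest and 5 lowest Pol II gene bodies, the 15 highest and 5 lowest Med7 promoter windows, the 10 genes highest and the 10 lowest in Med7 relative to Pol II, up to 4 members of each list (the 2 highest and the 2 lowest), med7, the genes that flank the centromeres, and the 3 highest tRNA, snoRNA and snRNA genes. The text gives most but not all of these, and any other gene is said to be chosen after its values were seen. Of the list names, tif5a and tif35 matched no gene and were left out. The alternatives were collapsing duplicates, scaling by the median 1 kb bin or by all reads in the file, other read shifts, other windows, other read minimums, no uniqueness filter, other size rules, a split or absent control, and another bin width.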

Results

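Chromatin of 3 kinds was sequenced from log-phase fission yeast: a bead control without antibody, and chromatin precipitated through RNA polymerase II (Pol II) or Med7. Med7 is a subunit of the Mediator complex, which links transcription factors to Pol II. The files listed 678947, 1829877 and 917064 aligned reads, which gave 50.3, 134.3 and 55.6 nuclear reads per kb. Each kind of chromatin has 1 library. No difference below has a replicate check, no p-value is given, and the 95% intervals in parentheses cover counting error only. Over 11880 unique bins of 1 kb, the SD over the mean of the reads was 1.35 in the Pol II library, 0.231 in the Med7 library and 0.22 in the control. The 5% of bins with the most reads held 24.6% of the Pol II reads, against 7.6% in the Med7 library and 7.4% in the control.

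The Pol II library addresses where the polymerase sat. Its highest gene bodies included those of glycolysis, fermentation and chaperone genes. The top gene was hsp9, a plasma membrane heat shock protein gene (SPAP8A3.04C, chromosome I, 5319957 to 5320676), at 16.2-fold over the control (12.2 to 22.1). Next came plb1, which encodes a lysophospholipase (SPAC1A6.04C, chromosome I, 1074331 to 1076693), at 14.3-fold (12.7 to 16.1). The glycolytic genes pgk1, for phosphoglycerate kinase (SPBC14F5.04C, chromosome II, 4157821 to 4159461), and eno101, for enolase (SPBC1815.01, chromosome II, 2201196 to 2202652), stood at 13.7-fold (11.7 to 16.0) and 13.3-fold (11.3 to 15.7). Of 4967 protein-coding genes measured, 337 were at 2-fold or more and 572 at 0.5-fold or less. Counting noise with every gene set at the control level gave 3.6 and 1.8 on average over 100 draws.

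The other 11 of the 15 highest gene bodies had varied functions. SPAC2H10.01, annotated as a transcription factor, was at 13-fold, adh1 for alcohol dehydrogenase at 12.2-fold and fba1 for aldolase at 11.5-fold. The Hsp70 gene ssa2 was at 11.5-fold (9.76 to 13.6), with 27 bp shared with ppe1. The phosphoglycerate mutase gene gpm1 was at 10.8-fold and shares 30 bp with mug106. The plasma membrane proton pump gene pma1 and the glycerol-3-phosphate dehydrogenase gene gpd1 were each at 10.3-fold, and the fatty acid desaturase gene ole1 at 10.2-fold. The cell wall glucanosyltransferase gene gas2 was at 9.94-fold (8.24 to 12.1), but 1355 bp of its transcript overlap tri1, so their reads cannot be separated. The uncharacterised gene SPAPB18E9.05C was at 9.25-fold (5.63 to 16.4) from 16 control reads, and hsp90, for the Hsp90 chaperone, at 9.06-fold (7.78 to 10.6).

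Of 13 measured genes of glycolysis and fermentation, 10 were at 2-fold or more and 0 at 0.5-fold or less, with a median log2 fold of 2.79 against -0.46 for matched random lists. The lowest members were hxk1, for hexokinase, at 1.06-fold and pdc201, for a pyruvate decarboxylase, at 0.504-fold (0.392 to 0.650). Of 14 chaperone genes, 13 were at 2-fold or more (median log2 1.84), from hsp9 and ssa2 down to hsp10 at 2.19-fold, which lies within nse1, and sti1 at 1.94-fold. Of 11 histone genes, 9 were at 2-fold or more (median 1.77), led by htb1 for H2B at 5.21-fold and hht3 for H3 at 4.92-fold, both with part of the transcript shared with another gene. The variants pht1 (H2A.Z) at 1.03-fold (0.742 to 1.46) and cnp1 (CENP-A) at 0.793-fold (0.598 to 1.06) had intervals that included 1. The cnp1 transcript shares 1014 bp with pth3 and adi1.

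Of 131 genes matched by the ribosomal protein name pattern, 85 were at 2-fold or more and 1 at 0.5-fold or less (median log2 1.13), with rpl39 at 5.09-fold and rpl22 at 4.55-fold. The lowest 2 matches, rpp1 at 0.525-fold and rpp21 at 0.407-fold, encode subunits of RNase P or RNase MRP and not of the ribosome. Translation factors had 3 of 6 measured genes at 2-fold or more (median 0.97), with the elongation factor gene tef3 at 4.38-fold and the eIF4A gene tif1 at 3.53-fold, and the release factor genes erf1 at 1.21-fold and sup35 at 1.19-fold. The list of membrane and methionine metabolism had 7 of 14 (median 1.1), with pma1 and the methionine synthase gene met26 (5.94-fold) at its top. At its bottom were the hexose transporter gene ght1 at 0.798-fold and lsd1 at 0.742-fold, which the annotation gives as a histone demethylase. The core stress list had 6 of 14 at 2-fold or more and 3 at 0.5-fold or less (median 0.79), from hsp9 and gpd1 to the sulfiredoxin gene srx1 at 0.465-fold and tms1 at 0.360-fold. Cell wall and flocculation genes had 5 of 13 (median 0.70), with the chitin synthase regulator gene cfh4 at 2.77-fold and adg1 at 2.73-fold against the flocculin-like genes pfl7 at 0.521-fold and pfl9 at 0.369-fold. The medians of these 8 lists all lay at the 100.0th percentile of their matched random lists.

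Of the lists for meiosis, mating, thiamine or phosphate, and iron, only meiosis lay below nearly all its random lists. Of 107 genes of meiosis and sporulation, 27 were at 0.5-fold or less and 1, mug106, at 2-fold or more (2.97-fold, 1.81 to 5.16), and that gene shares 30 bp with gpm1. The list median of -0.63 lay at the 0.2th percentile of its random lists. Of 14 measured genes in the mating list, 2 were high, namely the mating regulator ste11 at 2.89-fold and the pheromone protease gene sxa1 at 2.67-fold. Another 2 were low, with map2, for P-factor pheromone, at 0.237-fold (0.139 to 0.397), and the list median of -0.51 lay at the 26.3th percentile. That list also holds the metabolic genes fbp1 and inv1. In the list repressed by thiamine or phosphate (9 genes, median -0.74, 9.7th percentile), the phosphate transporter gene pho84 at 3.43-fold and the acid phosphatase gene pho1 at 2.36-fold contrasted with the thiamine-repressed genes pho4 at 0.444-fold and nmt1 at 0.332-fold. Of 10 iron uptake genes, 5 were at 0.5-fold or less, among them fio1 at 0.325-fold and the siderophore transporter gene str3 at 0.277-fold, and str1 was at 1.24-fold (list median -0.71, 6.3th percentile).

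Lists of regulators of chromatin and the cell cycle held 0 genes at 2-fold or more. The heterochromatin and RNA interference list (17 genes, median -0.80, 0.1th percentile, or 5.4th over coding sequence only) ran from raf2 at 0.897-fold to ago1, for Argonaute, at 0.398-fold. The CENP-A and kinetochore list (16 genes, median -0.74, 3.1th percentile) ran from spc7 at 0.872-fold to cnp20 at 0.343-fold. The median was -0.58 for 21 Mediator subunit genes (14.7th percentile), -0.56 for 12 targets of the G1/S factor MBF (25.1th percentile) and -0.25 for 8 auxotrophic marker genes (88.2th percentile). In those lists cdc22, for ribonucleotide reductase, was at 1.71-fold, yox1 at 0.265-fold, med11 at 1.1-fold and ade6 at 0.384-fold. Of the med11 transcript, 853 bp are shared with pkp1, so their reads cannot be separated. med7 itself stood at 0.812-fold (0.686 to 0.964), with 2996 bp of its transcript shared with ade8 and SPBC14F5.10C. The 5 lowest gene bodies of all were those of pdc102, for a pyruvate decarboxylase, at 0.210-fold (0.152 to 0.286), mzt1 at 0.220-fold, SPAPJ695.01C and SPAC9E9.17C at 0.224-fold and SPAC186.07C at 0.234-fold.

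Folds under 1 depend on the scaling, since a few genes take a large part of the Pol II reads. The median log2 fold of all gene bodies was -0.45. Scaling by the median 1 kb bin raised it by 0.43 and turned the split of 337 high and 572 low genes into 539 and 84, while collapsing duplicates gave 336 and 325. With median-bin scaling ght1, lsd1 and med7 moved to 1.08-fold, 1.00-fold and 1.1-fold, so low values are best read relative to that shift.

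**Figure D1:**
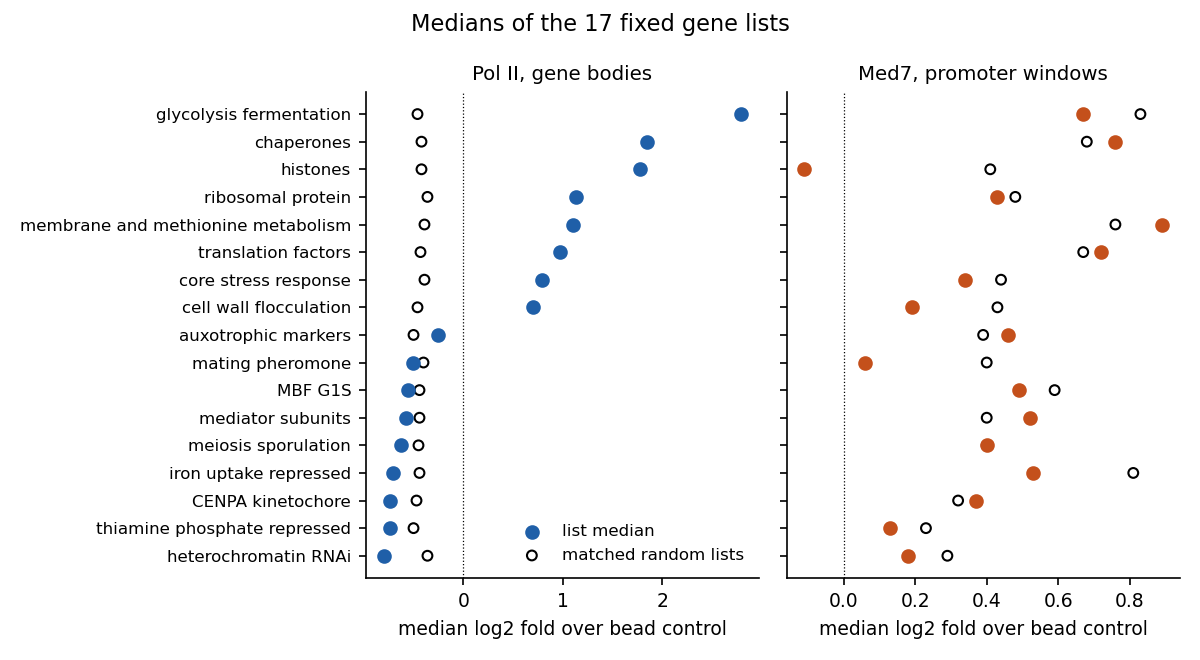
Median log2 fold over the bead control for the 17 gene lists, for Pol II in gene bodies (left) and Med7 in promoter windows (right), with 1 library each and different horizontal scales. Filled points are list medians and open circles the median of matched random lists; for Pol II the glycolysis list lies at 2.79 and the heterochromatin list at -0.80, and for Med7 the histone list lies at -0.11.

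Along genes, the ratio to the control was highest just upstream of the transcript start for Med7 and just before the transcript end for Pol II. Over 3102 protein-coding genes, Med7 reached 1.77-fold (bootstrap interval over genes 1.70 to 1.83) in the bin from -100 to -51 bp and was lowest, at 0.84-fold (0.80 to 0.87), at 700 to 749 bp inside the gene. The place of the Med7 summit comes from the control, whose RPM per gene was lowest in that bin, at 2.5, while Med7 had 4.41 there, less than its 4.83 at -200 to -151 bp or its 5.35 at 0 to 49 bp from the transcript end. Around the transcript end Med7 was again above the control, at 1.32-fold (1.27 to 1.36) in the bin from 0 to 49 bp. Pol II was lowest at -250 to -201 bp (0.72-fold, 0.69 to 0.76) and highest around the end at -100 to -51 bp (1.35-fold, 1.28 to 1.43). Its highest bin around the start, 1.05-fold (1.00 to 1.12) at 750 to 799 bp, moved with the processing (bins from -50 to 950 bp). Genes with neighbours near the transcript end or on the other strand were kept, so reads of neighbours can enter the end bins. Each value is a ratio of mean RPM, in which genes with many reads weigh most.

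**Figure D2:**
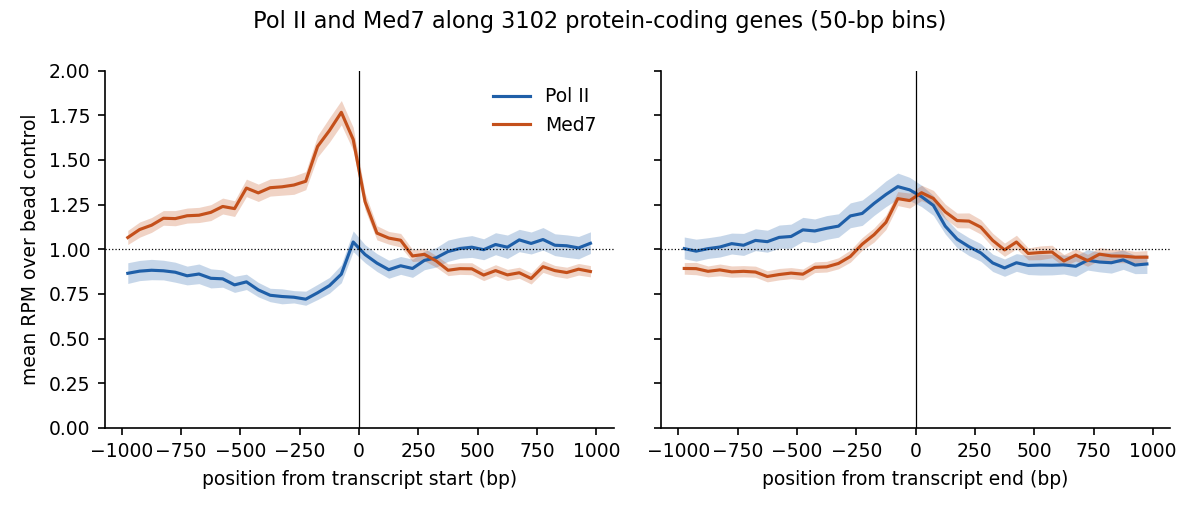
Mean RPM over the bead control (vertical) by distance from the transcript start (left) and end (right) in bp, over 3102 protein-coding genes in 50-bp bins, with bands for the 95% bootstrap interval over genes. Med7 reaches 1.77 at -100 to -51 bp from the start, and Pol II is lowest, at 0.72, at -250 to -201 bp and reaches 1.35 before the end.

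The Med7 library addresses where Mediator sat. Med7 was above the control in promoter windows across the genome and below it in gene bodies. Pooled over 5113 protein-coding genes, it was at 1.37-fold (1.36 to 1.38) in promoter windows and 0.913-fold (0.909 to 0.916) in gene bodies, against 0.876-fold and 1.02-fold for Pol II. Pooled values weigh genes with many reads most. The median Pol II fold was 0.762 in promoter windows and 0.735 in gene bodies, so the typical gene had no excess in its body. The Med7 and control libraries are scaled to the same nuclear total, so Med7 reads above the control outside gene bodies lower the body folds. The pooled body fold is thus relative to that excess and no separate evidence of depletion. Of 4944 promoter windows measured, 696 were at 2-fold or more and 14 at 0.5-fold or less. Counting noise with every window set at the control level gave 26.2 and 23.1 on average. The median promoter stood at 1.37-fold, however, and 18.0% of promoters simulated at 1.5-fold passed the rule. The 26.2 thus leaves out noise around the general shift. How many of the 696 exceed that shift was not tested. In gene bodies 27 of 4962 genes were high and 31 low.

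The promoter with the highest Med7 fold was that of rps801, for a ribosomal protein of the small subunit (SPAC2C4.16C, chromosome I, transcript 4286744 to 4287432), at 6.34-fold (3.01 to 15.4) from 56 reads against 8 in the control. The amino acid permease gene aat1 (SPBC359.03C, chromosome II, transcript 111007 to 113365) was at 5.85-fold (3.08 to 12.2). dre2, an anamorsin family gene whose promoter window overlaps SPBC337.11, was at 5.70-fold (2.55 to 15), and ntu1 at 5.18-fold (2.30 to 13.7). sdd3 was at 4.87-fold (2.26 to 12.0), with a window that overlaps its divergent neighbour mug151. The divergent pair rtf1 and sec24, the latter for a coat protein of secretory vesicles, had windows on the same region at 4.73-fold and 4.44-fold. Also among the 15 highest were mrpl50 and the kinase gene nak1, SPAC11D3.16C and mug16 (each at 4.53-fold), the copper chaperone gene atx1 at 4.43-fold, SPAC17A2.10C at 4.35-fold, ofd1, for a dioxygenase, at 4.33-fold, and mto2, for a gamma tubulin linker, at 4.14-fold. The lowest were rmi1 at 0.272-fold (0.114 to 0.587), which overlaps rpl2002 and myh1, then the glycerophosphodiester transporter gene tgp1 at 0.412-fold, SPAC4F10.17 at 0.415-fold, SPAC186.07C at 0.416-fold and SPBC32F12.07C at 0.423-fold. These windows hold few reads, and the order among them lies within their intervals. The 15 highest had 5 to 12 control reads and 24 to 71 Med7 reads. The 5 lowest had 30 to 48 control reads and 9 to 22 Med7 reads. Medians over all measured promoters were 25 control reads and 38 Med7 reads. The ranking thus depends on control reads as well as on Med7 reads.

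For 6 of the 8 lists that were high for Pol II, Med7 promoter medians lay between the 10.8th and 85.3th percentiles of their random lists. Of 139 promoters matched by the ribosomal protein pattern, 16 were at 2-fold or more and 1, rps1602 at 0.436-fold, at 0.5-fold or less, with a median log2 fold of 0.43 against 0.48 for matched random lists (10.8th percentile). Besides rps801, rps1702 was at 2.90-fold. Glycolysis and fermentation genes had 4 of 15 at 2-fold or more (median 0.67, 13.5th percentile), with pdc101, for pyruvate decarboxylase, at 3.99-fold (1.98 to 8.89) and pgk1 at 2.54-fold, while gpd3 was at 0.755-fold (0.426 to 1.33). Chaperones had 2 of 13 (median 0.76, 72.9th percentile), namely ssa2 at 2.77-fold and ssa1 at 2.59-fold, and hsp16 was at 1.00-fold. Translation factors had 4 of 11 (median 0.72, 62.0th percentile), with eft201 at 2.29-fold and tef3 at 2.27-fold. Membrane and methionine metabolism had 6 of 14 (median 0.89, 85.3th percentile), with the alcohol dehydrogenase gene adh4 at 3.08-fold and lsd1 at 2.35-fold.

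The core stress list had 1 of 14, the stress transcription factor gene atf1 at 3.25-fold (1.87 to 5.94), and a median of 0.34 (19.1th percentile). Meiosis and sporulation genes had 16 of 106 (median 0.40, 48.6th percentile), among them mug16 and mug151 (3.72-fold). Mediator subunit genes had 3 of 20 (median 0.52, 89.3th percentile), with srb4 at 2.15-fold and med15 at 2.11-fold, and med7 was at 1.58-fold (0.963 to 2.63). CENP-A and kinetochore genes had 3 of 15 (median 0.37, 66.8th percentile), with mis6 at 2.72-fold and the CENP-A chaperone gene scm3 at 2.22-fold, while mis18 was at 0.560-fold (0.309 to 0.993). Heterochromatin and RNA interference genes had 0 of 17 (median 0.18, 17.6th percentile), with tas3 highest at 1.95-fold. The medians were 0.49 for 12 MBF targets (21.2th percentile), with cdt2 at 2.08-fold, 0.13 for 9 genes repressed by thiamine or phosphate (25.4th percentile), with tgp1 as the 1 low promoter, 0.46 for 8 auxotrophic markers (71.3th percentile), with arg3 at 2.10-fold, and 0.53 for 10 iron uptake genes (3.8th percentile), with the iron regulator gene fep1 at 3.29-fold.

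Lists with Med7 medians below nearly all matched random lists were histones (11 genes, median -0.11, 0.0th percentile), the mating list (15 genes, 0.06, 0.7th percentile) and cell wall and flocculation genes (17 genes, 0.19, 1.8th percentile). The mating list also holds the metabolic genes fbp1, at 0.612-fold (0.353 to 1.04), and inv1. Among histones, cnp1 was at 1.98-fold (1.24 to 3.25) and hht2 at 0.705-fold, and 0 of 11 reached 2-fold with the lower bound above 1. Several histone genes are divergent pairs, so that a window of hht2 reaches into hhf2. In a narrower window of -250 to +50 bp the histone median was 0.88, at the 58.4th percentile, and the mating and cell wall lists moved to the 12.8th and 6.7th percentiles. With duplicates collapsed the histone median was 0.16, at the 3.6th percentile. In the mating list ste6 was at 2.63-fold and map2 at 0.529-fold (0.293 to 0.930), and among cell surface genes pfl4 was at 3.43-fold and the septum glucanase gene eng1 at 0.668-fold (0.395 to 1.12).

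The Med7 counts depend on the scaling, because the library held many mitochondrial reads. Scaling by all reads in the file lowered the median log2 fold of promoter windows by 0.29, from 0.45 to 0.16, and turned 696 high and 14 low promoters into 252 and 43. With collapsed duplicates 576 promoters were high, 503 of them among the 696. Without the read shift 594 were high, 447 of them among the 696, and from -250 to +50 bp 978 were high, 425 of them among the 696.

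Across genes, Med7 at the promoter and Pol II in the gene body were almost unrelated. Over 4895 genes, which are not independent replicates, Spearman's rho was 0.10 (bootstrap interval 0.07 to 0.13) and Pearson's r 0.09 (0.06 to 0.11). The highest Pol II genes had ordinary Med7 promoters: pooled over the top 5% of genes by Pol II (245 genes, Pol II 4.48-fold), Med7 was at 1.37-fold (1.32 to 1.41) in promoter windows, against 1.29-fold (1.27 to 1.31) in the lowest 20% (979 genes, Pol II 0.478-fold). In gene bodies Med7 was lowest in the same top class, at 0.821-fold (0.807 to 0.835). Simulated unchanged libraries that share the control gave a mean rho of 0 and at most 0.047, and a covariance of 0 against 0.033 observed. With the control reads split between the folds rho was 0.07, and without the control it was -0.07. Of 334 genes high for Pol II and 687 high for Med7, 62 were shared, where independent lists would share 46.9. Among low genes, 5 were shared, where 1.6 would be. Part of either excess may come from the shared control.

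**Figure D3:**
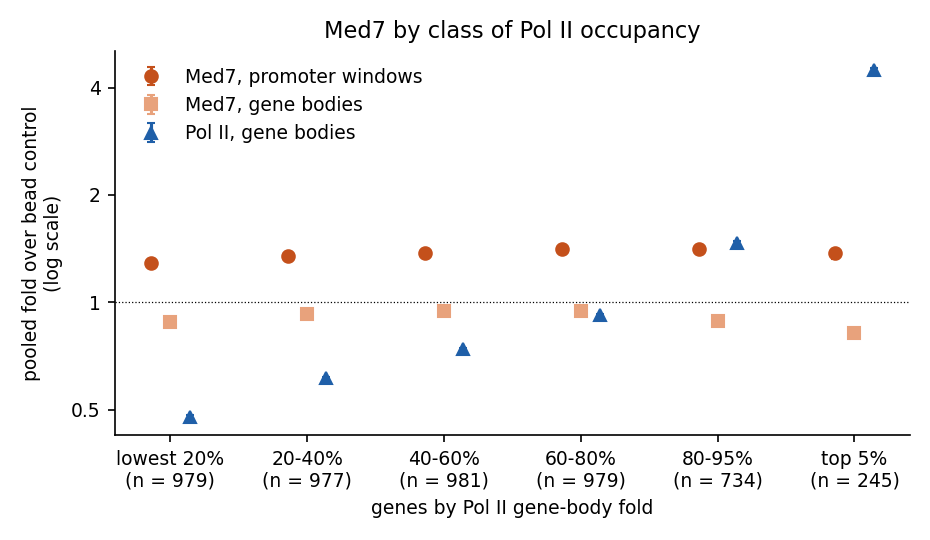
Pooled fold over the bead control (log scale) of Med7 in promoter windows, Med7 in gene bodies and Pol II in gene bodies, for genes in 6 classes by Pol II gene-body fold, with the number of genes under each class and bars for 95% counting intervals, which are smaller than most points. Pol II spans 0.478 to 4.48 while Med7 in promoter windows stays between 1.29 and 1.41.

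Among 962 genes at 2-fold or more in at least 1 of the measures, those with the most Pol II for their Med7 were plb1 (Med7 promoter 0.604-fold, 0.420 to 0.863), adh1 (1.09-fold), SPAC2H10.01 (1.19-fold), eno101 (1.26-fold), SPAPB18E9.05C (0.929-fold) and gpd1 (1.09-fold). hsp9, at 1.72-fold (0.959 to 3.17), but2 at 0.777-fold and ole1 at 1.22-fold followed, and SPAC343.20, at 1.02-fold, overlaps 1712 bp of rds1. At the other end were genes with a high Med7 promoter over a Pol II body below the control: mzt1, for a spindle organising protein, at 2.21-fold (1.34 to 3.76) against 0.220-fold, the Ran exchange factor gene pim1 at 3.93-fold against 0.414-fold, mrpl50 at 4.53-fold against 0.481-fold and the glyoxylate reductase gene gor2 at 2.93-fold against 0.332-fold. The serine acetyltransferase gene SPAC1039.08 was at 3.81-fold against 0.450-fold, the proline synthesis gene pro3 at 3.96-fold against 0.478-fold, but1 at 3.12-fold against 0.391-fold, gup1 at 4.03-fold against 0.515-fold and the nicotinic acid transporter gene tna1 at 2.36-fold against 0.303-fold. The promoter windows of mzt1, mrpl50, SPAC1039.08, pro3, but1 and gup1 overlap a neighbouring gene.

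The series is about Mediator and CENP-A at centromeres, so the centromeres were compared with the rest of the genome. Med7 was above the control at the central core of centromere 2, and Pol II was below it at all 3 cores. The core of centromere 2 (chromosome II, 1620807 to 1627609, 6803 bp) lies between rpb1 and yox1 and was the only core with 100% unique positions. There Med7 was at 1.73-fold (1.49 to 2.01) from 524 reads against 274 in the control, and Pol II at 0.536-fold (0.458 to 0.628). In 14 stretches of this core, Med7 ranged from 0.958-fold to 3.14-fold and Pol II from 0.360-fold to 0.748-fold. Of 10000 random nuclear windows of that length outside the centromeres, 100% had a lower Med7 fold and 4.41% a lower Pol II fold, with medians of 0.994-fold for Med7 and 0.801-fold for Pol II. The random windows were not matched on base composition, and the core has 28.6% GC.

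The other cores gave smaller or less certain Med7 values. At centromere 1 (chromosome I, 3769078 to 3773195, 23.4% unique positions) Med7 was at 1.37-fold (0.926 to 2.04) and Pol II at 0.440-fold (0.290 to 0.670), from 45 control reads. At centromere 3 (chromosome III, 1097071 to 1101923, 39.9% unique) Med7 was at 1.09-fold (0.852 to 1.39) and Pol II at 0.380-fold (0.294 to 0.491). Of random windows of the same lengths, 97.65% had a lower Med7 fold than core 1 and 72.64% than core 3, and 1.5% and 0.31% a lower Pol II fold. Few unique positions give these core folds a larger counting error than fully unique windows of that length would have. Their percentiles are therefore uncertain. Pooled over the 3 cores, Med7 was at 1.52-fold (1.35 to 1.71) and Pol II at 0.483-fold (0.426 to 0.548). Pol II folds here carry the scaling shift and stood at 0.652-fold pooled with median-bin scaling.

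In the outer regions, which hold the heterochromatic dg and dh repeats and run to the flanking genes, Med7 was at the control level and Pol II below it. Pooled over 132228 bp with 11.4% unique positions, Med7 was at 1.02-fold (0.945 to 1.1) and Pol II at 0.419-fold (0.388 to 0.454), or 0.566-fold with median-bin scaling. Scaled by all reads in the file, Med7 was below the control, at 0.835-fold (0.772 to 0.903). These values describe the unique parts of the regions only, which may lie beside the repeats. The inner repeats had 1.32% unique positions and 9 control reads in all. Pooled over them, Med7 was at 3.12-fold (1.45 to 7.45) from 31 reads. The Pol II interval there, 0.555 to 2.89 from 29 reads, included 1. With so few control reads and unique positions, the inner repeat values are uncertain. Of the genes that flank the centromeres, rpb1, for the largest Pol II subunit, was at 1.70-fold for Pol II and 1.61-fold (1.02 to 2.58) for Med7 at its promoter, and the permease gene per1 at 1.31-fold and 2.24-fold (1.29 to 4.04). Med7 promoter intervals included 1 for yox1 (1.42-fold), emc5 (1.46-fold), chk1 (1.11-fold) and ppc1 (1.27-fold), whose Pol II folds were 0.265, 0.708, 0.427 and 0.944. The chk1 transcript shares 2693 bp with meu27.

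**Figure D4:**
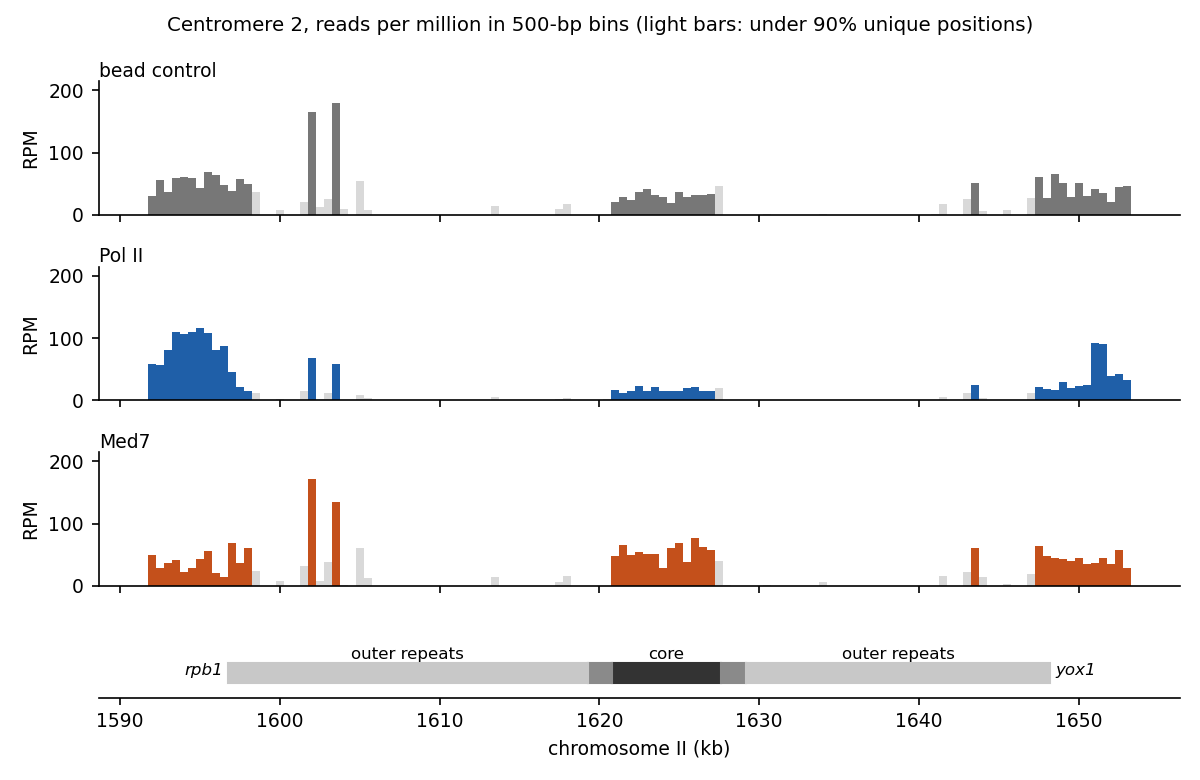
RPM in 500-bp bins (vertical) along centromere 2 on chromosome II (horizontal, kb) in the bead control, Pol II and Med7 libraries, with light bars where under 90% of positions are unique and a map of the core (black), inner repeats (dark grey) and outer repeats (light grey) below. Over the core, Med7 is at 1.73-fold and Pol II at 0.536-fold of the control, and most of the outer repeats hold almost no reads because only unique positions are listed.

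The classes of short non-coding RNA genes differed in Pol II. The 6 snRNA genes were at 4.14-fold (3.11 to 5.63) for Pol II pooled over their bodies, led by snu1 at 7.79-fold (3.48 to 21.6), snu5 at 7.04-fold and snu2 at 4.58-fold. The 66 snoRNA genes were at 2.09-fold (1.94 to 2.26), with sno20 at 5.73-fold (2.54 to 16.0). The 171 tRNA genes, which RNA polymerase III transcribes, were at 0.324-fold (0.296 to 0.353), and their 3 highest were SPBTRNAGLY.09 at 0.444-fold (0.216 to 0.923), which turned to 1.62-fold (0.445 to 8.86) without the read shift, SPATRNACYS.02 at 0.408-fold and SPATRNALEU.03 at 0.401-fold. Only 4 tRNA bodies had 20 reads, so these are mostly pooled values. Med7 was also below the control in tRNA bodies, at 0.635-fold (0.578 to 0.697), but not in snoRNA bodies, at 1.03-fold (0.932 to 1.13). In promoter windows Med7 was at 1.24-fold (1.17 to 1.31) for snoRNA, 1.13-fold (0.921 to 1.40) for snRNA and 1.03-fold (0.989 to 1.07) for tRNA genes. The highest tRNA gene there was SPBTRNAGLU.05 at 1.86-fold (1.06 to 3.35).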

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

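The test of capture at highly transcribed genes was chosen after the result was seen; the other tests here were chosen before. Mitochondrial reads, which enter only the alternative scaling by all reads in the file, stood above the control in both ChIP libraries: 23.8% of the reads in the Med7 library (Wilson 95% interval 23.72 to 23.89) and 7.73% in the Pol II library (7.69 to 7.77), against 6.84% (6.78 to 6.90) in the control.

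Med7 over the control was higher in promoter windows than in gene bodies. At equal GC, 200-bp windows just upstream of transcript starts exceeded coding windows by 0.70 in log2 Med7 fold (bootstrap interval 0.66 to 0.74), which argues against GC bias as the whole of the pattern, although GC took up part of an unmatched difference of 1.06. Upstream windows also exceeded convergent intergenic windows of equal GC by 0.49 (0.41 to 0.56), which argues against a better recovery of all intergenic DNA as the whole of the pattern, although convergent windows, at 1.27-fold, also stood above the 0.804-fold of coding windows. Over the bodies of the 5% of genes with the most Pol II, Med7 was at 0.894 times the fold of the other genes (0.869 to 0.917), but values by Pol II class were known when this test was chosen and it does not cover promoters, so it leaves open whether highly transcribed promoters are captured without Med7. That the pattern reflects Mediator at promoters stays a hypothesis, since the ratio peaks where control reads are fewest (RPM per gene 2.5) and not where Med7 reads are most, and an untagged strain on IgG beads, which could show bead or open-chromatin background, was not analysed here.

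Med7 at promoters and Pol II in gene bodies were only weakly correlated across genes. If counting noise hid a strong relation, the correlation corrected for the split-read reliability of both folds would be at least 0.5. The corrected rho was 0.13 (0.08 to 0.18) with a split-half rho of 0.26 for Med7 and 0.76 for Pol II, and 0.18 (0.11 to 0.26) with duplicates collapsed, so noise does not account for the low value. Whether occupancy differs by gene in a way unrelated to Pol II, or by technical differences in the precipitation of Med7, was not tested.

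Med7 over the control was above 1 at central core 2. The core is AT-rich, and against all other 200-bp windows of the same GC its log2 Med7 fold was higher by 0.35 (0.04 to 0.65), down from 0.79 without matching. Against convergent intergenic windows of the same GC the difference was also 0.35 (0.07 to 0.66). Both intervals lie above 0 but reach below the 0.1 set for excluding these explanations, because the core holds only 34 such windows. The tests thus cannot tell whether GC bias or intergenic recovery accounts for some of the excess or for nearly all of it. The tagged strain and the beads differ from the control as well, and their effect stays open.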

How the results depend on the processing

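No paired analysis was possible because each group has 1 library. Keeping only reads at unique positions, for cores and repeats, changed nothing by construction, since the files list uniquely placed reads only, so that alternative gives no separate value. Except where a cause is given, the cause was not tested.

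Genes high and low for Pol II, 337 and 572, became 539 and 84 with median-bin scaling, 523 and 1884 at 1.5-fold and 143 and 42 at 3-fold, and low genes became 325 with duplicates collapsed and 922 over coding sequence. Median-bin scaling raises every Pol II fold by the same factor, which shows the cause there. Promoters high and low for Med7, 696 and 14, became 252 and 43 when scaled by all reads in the file and 3 and 0 with a minimum of 100 reads. Mitochondrial reads enter the file totals, and few promoter windows hold 100 reads, which shows the cause of those changes. The counts became 1265 and 29 at 1.5-fold and 99 and 1 at 3-fold. From -250 to +50 bp they became 978 and 36, with 425 of the high promoters among the 696. Without the read shift they became 594 and 14, with 447 of the high promoters among the 696.

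Spearman's rho of 0.10 was -0.07 without the control, -0.60 with a minimum of 100 reads (19 genes), 0.02 with both proteins in gene bodies and 0.40 with both in promoter windows. In the last pair of settings both folds use the same control reads, so that simulated unchanged libraries gave 0.59 in each, and splitting the control gave -0.09 in gene bodies and 0.09 in promoter windows. The covariance in promoter windows was 0.127, against 0.091 in the simulated libraries and 0.035 with the control split. In gene bodies the covariance was -0.009, against 0.029 and -0.039. For rho, other settings gave 0.07 to 0.11.

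At the cores, Pol II pooled was 0.567 with duplicates collapsed and 0.652 with median-bin scaling, and Med7 was 1.24 scaled by all reads. In outer regions Pol II was 0.474 and 0.566 under those settings, and Med7 0.835. The highest Pol II bin around the start began at 680 bp in 20-bp bins, -50 bp with duplicates collapsed and 950 bp without shift, at 1.07, 1.08 and 1.07-fold, while the Med7 summit stayed within 50 bp.

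Besides these, some pooled folds, list medians and named genes changed side of the control. With median-bin scaling, Pol II was 1.18-fold in coding promoter windows, 1.19-fold in long non-coding RNA bodies, 1.02-fold and 1.09-fold in bodies and promoters of other non-coding RNA genes, and 1.08, 1.00 and 1.1-fold for ght1, lsd1 and med7. Over coding sequence Pol II pooled was 0.965-fold, and from -250 to +50 bp the Med7 histone median was 0.88. Scaled by all reads, Med7 promoters were 0.922-fold for 5S rRNA, 0.869-fold for long non-coding RNA and 0.927-fold for pseudogenes. Without shift, Pol II at SPBTRNAGLY.09 was 1.62-fold.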

Other observations

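Long terminal repeats, the short remnants of retrotransposons, had more Med7 than any gene class pooled over bodies: 238 elements stood at 2.13-fold over the control (2.00 to 2.26). Among 94 elements with enough reads and unique sequence, 39 were at 2-fold or more and 0 at 0.5-fold or less, with a median of 2.11-fold and a highest value of 9.97-fold. Pol II over the same class was at 0.743-fold (0.698 to 0.791), with 0 of 89 measured elements at 2-fold or more and 17 at 0.5-fold or less. The repeats have 32.6% GC, close to the 32.9% of windows just upstream of genes, where Med7 was at 1.67-fold. Scaling by all reads in the file left the class at 1.74-fold for Med7, and median-bin scaling put Pol II at 1.00-fold. The 13 Tf2 retrotransposon genes, which are nearly identical copies, held only 25 control reads in their bodies and gave 1.01-fold (0.571 to 1.81) for Med7.

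For Med7 in bodies no other class reached 2-fold. Pseudogenes (32) were at 0.486-fold (0.450 to 0.525) for Pol II and 0.901-fold (0.830 to 0.977) for Med7 in bodies, and 5S rRNA genes (36) at 0.313-fold (0.267 to 0.367) and 0.582-fold (0.489 to 0.691). Long non-coding RNA genes (7133), which can share DNA with coding genes or their flanks, were at 0.884-fold for Pol II and 1.00-fold for Med7 in bodies. A class of 38 other non-coding RNA genes was at 0.754-fold (0.630 to 0.906) for Pol II and 1.35-fold (1.11 to 1.64) for Med7. In promoter windows Med7 was at 1.13-fold for pseudogenes, 1.13-fold for 5S rRNA genes, 1.06-fold for long non-coding RNA genes and 1.28-fold for the other non-coding RNA genes.

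Within gene bodies, where Med7 was mostly below the control, several lists stood apart from their matched random lists. Median log2 Med7 folds in bodies were -0.64 for glycolysis and fermentation (against -0.18 for matched random lists), -0.56 for translation factors (-0.16) and -0.44 for ribosomal protein genes (0.07), each at or below the 0.1th percentile. The core stress list (-0.35, 1.0th percentile) and membrane and methionine metabolism (-0.37, 1.2th percentile) were low as well. MBF targets, whose Pol II median was -0.56, were also low for Med7 (-0.38, 0.9th percentile), while chaperones (-0.21, 21.9th percentile) and histones (-0.03, 28.2th percentile), whose Pol II was high, lay within the range of random lists. Meiosis and sporulation genes stood at 0.10, at the 100.0th percentile. The random lists were not matched on GC, with which the Med7 fold varies. At equal GC the log2 difference between upstream and coding windows fell from 1.06 to 0.70. How much of the list differences GC accounts for was not tested. The list values were looked up after the main results and have no replicate check.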
